A study of Mus musculus with 3 samples.

How the data were processed

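Cultured spleen cells of male MRL/MpJ mice aged 6 months were kept for 3 h with PBS, with urine of MRL/MpJ mice, or with urine of MRL/MpJ-Faslpr/lpr mice (lpr urine below), a strain that lacks functional Fas and develops lupus-like autoimmune disease. Per the labels' protocols, urine from 6 male donors per strain was pooled, spun and passed through a 0.22 µm filter, cells were held in 500 µL of medium per well, and labelled cRNA was made from 0.05 µg of total RNA. The labels do not give the ratio of urine to medium, its osmolality or pH, its endotoxin content, the number of spleens, or the number of cells alive after contact. There was 1 array per condition, so no comparison had a replicate check, no p-value or standard error was possible, and a difference between 2 arrays cannot be split into treatment, culture well and array.

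Per the file headers, the 3 deposited files hold 1-colour (Cy3) Agilent arrays of design 074809, all on 1 slide and from 1 scan, read with Feature Extraction 12.0.3.1, and the submitters' processing notes name the same tool and version. Per the file headers, the deposited values are intensity in arbitrary brightness units. The processed signal is an intensity from which the authors' software had subtracted background within the array, with spatial and multiplicative detrending and with very low values replaced by a surrogate; it was not normalised between arrays. Mean spot signal and local background are unprocessed intensity values, per the file headers. Probe positions are those of the file headers' annotation on mouse build mm9 (NCBI build 37) and are given 1-based.

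Each array had 62976 spots, of which 59305 were not controls and carried 56605 probes. A total of 300 probes were spotted 10 times and were averaged after flagged spots were removed. The 6 probes whose spots were all flagged on an array were left out, which left 56599. Symbols came from the files and were checked against a table of mouse RefSeq genes on GRCm38, which was used for names and neighbours and not for coordinates. Of the probes, 35405 matched it and 1 symbol was updated. Each gene was read from the probe that was well above background, by the software's own call, on most of the 3 arrays, and among ties from the brightest one. This gave 36609 genes, 20197 of them with a gene name, and 12055 had several probes.

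Log2 processed signal minus the array's 75th percentile was the level, and the difference of 2 levels was the log2 difference. A gene counted as higher or lower where it was well above background on both arrays and differed at least 2-fold. A gene measured on 1 of the 2 arrays was counted apart, with a bound taken against the gene's own signal on the other array or, where that was lower, against the lowest signal that the software called well above background there. Because the lowest such signal lies lower on the scaled PBS array than on the scaled urine arrays, the size of these bounds against PBS depends on the scaling. Levels of different probes were not compared with each other. Named genes were, per comparison, the 10 highest and 10 lowest among genes with a gene name that were well above background and unsaturated on both arrays and whose brighter level reached that array's median of measured genes, the 3 largest bounds each way, the up to 4 largest differences in each list, and Fas and Fasl.

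The 22 gene lists were inflammatory cytokines, chemokines, NF-kB feedback and target genes, microbial-product response of phagocytes, type I interferon response, interferon-gamma response, immediate early genes, lymphocyte activation, T cell cytokines, lymphoid tissue organisation, osmotic stress, heat shock, unfolded protein and amino acid stress, oxidative stress NRF2 targets, p53 targets and apoptosis, metal response, glucocorticoid targets, aryl hydrocarbon receptor targets, cholesterol synthesis, glycolysis and hypoxia, cell cycle, and housekeeping. The 14 marker lists were B cells, plasma cells, T cells, NK cells, monocytes and macrophages, neutrophils, dendritic cells, erythroid cells, platelets and megakaryocytes, stromal cells, endothelial cells, urinary tract epithelium, male accessory glands, and major urinary proteins and liver. Some genes sat in more than 1 list: Hspa1b and Hspa4l in osmotic stress and heat shock, Sgk1 in osmotic stress and glucocorticoid targets, Tnfsf11 in T cell cytokines and lymphoid tissue organisation, and Irf4 in lymphocyte activation and plasma cells. A list's median was taken over members well above background on at least 1 of the 2 arrays, members measured on 1 array entering with the processed signal of the other. It was placed among the medians of 10000 random lists of the same size and level (20 level bins). The percentile describes these arrays only. Members counted as higher or lower by 2-fold are those measured on both arrays, under 75th percentile scaling. Spike-in scaling moves all members toward lower against PBS, so these counts change with it. Lists with fewer than 4 members measured on at least 1 array got values alone, and a list was singled out below 2.5% or above 97.5%.

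The lists, the named-gene rule and these alternatives were fixed before the data were examined: normexp background correction of mean spot signal (offset 50, limma 3.58.1 in R 4.3.3), scaling by the array median, quantile normalisation, genes above background on at least 1 array, no filter on dim genes, only genes above the median level, the mean of a gene's probes, and a 1.5-fold rule. Added after the data were seen were scaling on the 8 E1A spike-in probes measured on all 3 arrays, leaving out unnamed and ribosomal protein genes, list medians over genes measured on both arrays, and list medians with dim levels raised to the lowest measured level of their array. Scaling by the array median shifted every log2 difference by -0.37 for MRL/MpJ urine against PBS and by -0.39 for lpr urine against PBS. Spike-in scaling shifted them by -0.90 and -1.00. Between the urines the shifts were -0.02 and -0.10. The labels do not say at which step the spike-ins were added.

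The remaining calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The script was tested on simulated data with the spot noise of these arrays. Of 100 genes altered by 1.5 on the log2 scale, it recovered 98 in MRL/MpJ urine against PBS (19639 genes), 99 in lpr urine against PBS (19368 genes) and 96 in lpr urine against MRL/MpJ urine (20012 genes). All 100 genes altered by 3 were recovered in each. Among unchanged genes, 6, 6 and 7 were called in these comparisons from spot noise alone. The cholesterol synthesis list was shifted as well, and 2, 0 and 1 of the other lists lay in a tail. Spot noise covers repeated spots on an array and leaves out differences between wells, labelling reactions and arrays. Unnamed transcripts were counted but not described one by one, and some genes that the rule named are not reported here.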

Results

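Gene expression was measured on 3 single-colour arrays of cultured MRL/MpJ spleen cells, 1 each after 3 h with PBS, with MRL/MpJ urine and with lpr urine. All cells came from mice with an intact Fas gene, and only the urine donors differed at Fas. The 75th percentile of the processed signal was 157.5 intensity units on the PBS array, 86.6 on the MRL/MpJ urine array and 75.7 on the lpr urine array. Probes well above background made up 59.0%, 56.4% and 55.3% of those on the respective arrays, which gave 21317, 20811 and 20472 measured genes. The 8 E1A spike-ins, synthetic transcripts added in fixed amounts, were 0.05 higher with MRL/MpJ urine and differed by -0.06 with lpr urine in median log2 processed signal before scaling. The spread of repeated spots of 1 probe within arrays, most of them bright, would give a log2 difference of any 2 arrays a median SD of 0.06. That SD was 0.12 at log2 signals of 5 to 8 and 0.285 below 5, and it leaves out noise between arrays. With 1 array per condition, every difference below describes these arrays, and no replicate can show how much of it would recur in other wells or mice.

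The first comparison asked how spleen cells differ after contact with urine of the strain they came from. Fgf18, which encodes a fibroblast growth factor, was 631-fold higher on the MRL/MpJ urine array than on the PBS array (log2 difference 9.30; probe on chromosome 11, 33017441 to 33017500, mm9). Lsmem1, a gene for a small membrane protein, was 603-fold higher (9.24; chromosome 12, 40903148 to 40903207). Gadd45g, a stress-induced inhibitor of cell growth, was 189-fold higher and read 65072 intensity units against 626 with PBS (7.56; chromosome 13, 51943733 to 51943792). Arc, an activity-induced gene best known from neurons, was 133-fold higher (chromosome 15, 74499597 to 74499656), and Hexim1, whose protein holds the elongation factor P-TEFb inactive, was 114-fold higher (chromosome 11, 102980827 to 102980886). Ifna5, an interferon alpha gene read by 1 probe, was 113-fold higher (chromosome 4, 88481935 to 88481994). With normexp background correction the difference of Fgf18 was 6.09, so that folds of genes near background on the PBS array, where Fgf18 read 8.53 intensity units, are uncertain in size. Orc1, which encodes part of the origin recognition complex, differed by 6.60 on its brightest probe and by 3.67 on its other probe.

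At the other end, several hypoxia-induced genes were among the lowest. Hilpda, a hypoxia-induced lipid droplet gene, was 21.5-fold lower with MRL/MpJ urine than with PBS (chromosome 6, 29225127 to 29225186), Slc16a3, the lactate exporter MCT4, was 18.6-fold lower (chromosome 11, 120820023 to 120820082), and Egln3, a hypoxia-induced prolyl hydroxylase, was 15.7-fold lower (chromosome 12, 55280953 to 55281012). Ccl4, a chemokine that attracts lymphocytes and monocytes, was 19.5-fold lower (chromosome 11, 83478052 to 83478111). Lrrc32, which encodes the latent TGF-beta carrier GARP of regulatory T cells, was 25.1-fold lower (chromosome 7, 105650282 to 105650341), Cables1 was 25.2-fold lower, Ramp3 was 19.3-fold lower, and F10, the gene of coagulation factor X, was 16.8-fold lower.

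Several of the most distant genes rested on a single probe among others that differed. Pycard, the gene of the inflammasome adaptor ASC, was 294-fold higher on a probe at chromosome 7, 135140025 to 135140084, and differed by 0.36 on a probe for the opposite strand. Cracr2b spanned 0.27 to 7.39 over 4 probes, some of them on opposite strands, Rbm44 differed by 6.88 and 0.94, and Dmrtb1 by -4.95 and 1.46. For Pycard and Cracr2b, probes on opposite strands cannot all read the gene's own transcript, and which ones do was not determined. Among genes measured on the urine array and not on the PBS array, Smim41 was at least 290.0-fold higher and Hcrt, the hypocretin precursor gene, at least 98.996-fold. Among those measured on the PBS array alone, Lyzl6 was at least 60.5-fold lower, Eml1 at least 19.6-fold and Gdf15, a stress-induced cytokine of the TGF-beta family, at least 17.6-fold.

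The heat shock list lay above its random lists with MRL/MpJ urine. In it, 10 of 17 members were at least 2-fold higher and 0 were lower, with a median of 1.05 that remained positive, at 0.15, under spike-in scaling and lay above 99.99% of random lists of the same level. Its largest differences were those of the inducible HSP70 genes Hspa1b (4.42) and Hspa1a (3.19), of Hsp90aa1 (2.45) and of the HSP70 co-chaperone Bag3 (2.24). In the osmotic stress list, Slc5a3, the gene of a myo-inositol importer that hypertonic medium induces, was higher by 4.56 and the salt-regulated kinase gene Sgk1 by 2.75, whereas the glucose transporter gene Slc2a1 differed by -2.67. That list as a whole had a median of 0.37 (percentile 97.45), which was -0.53 under spike-in scaling. In unfolded protein and amino acid stress, members went both ways: Ppp1r15a was higher by 3.69, while the amino acid stress genes Chac1 and Trib3 differed by -3.88 and -3.87. Ddit3 differed by 3.58 on its brightest probe and by -1.24 on another.

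The type I interferon response lay above its random lists as well. Of 22 members measured on both arrays, 9 were at least 2-fold higher and 0 were lower (median 0.94, above 99.98% of random lists, 97.2% of them when only genes above the median level entered, and 0.04 under spike-in scaling). Isg15, a ubiquitin-like antiviral modifier, was higher by 4.03, the antiviral GTPase gene Mx1 by 3.02, Oas2, a sensor of double-stranded RNA, by 2.90 and Cmpk2 by 1.65. In the interferon-gamma response, 6 of 17 members were at least 2-fold lower and 3 were higher, with a median of -0.63 (percentile 1.63), a position that reached percentile 16.1 under the alternatives and left the lower tail with normexp background correction and with the mean of a gene's probes. The GTPase genes Ifi47 and Irgm2 differed by -1.73 and -1.66, and Ciita, the regulator of MHC class II genes, was higher by 1.77 on its brightest probe and by 0.34 on its lowest. Ifng itself was higher by 3.54. The T cell cytokines had a median of 1.77 over 7 measured members (percentile 99.65), which left the upper tail under 3 alternatives and was 95.6 at the lowest. Of the 5 members measured on both arrays, 2 were at least 2-fold higher and 1 was lower. Tnfsf11, the RANK ligand gene, was higher by 1.77 and the cytotoxic granule gene Gzmb differed by -2.36.

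Lymphocyte activation genes were mostly lower with MRL/MpJ urine. Of 19 members measured on both arrays, 13 were at least 2-fold lower and 3 were higher, with a list median of -1.57 that lay below all 10000 random lists. Irf4, a transcription factor induced by antigen receptors, differed by -3.21, the activation marker Cd83 by -3.15, the inhibitory receptor gene Pdcd1 by -3.02 and the co-stimulatory receptor gene Tnfrsf9 by -2.58. NF-kB feedback and target genes had 10 of 21 such members at least 2-fold lower and 4 higher (median -1.01, percentile 0), including the NF-kB subunit gene Rel at -2.74 and the feedback inhibitor gene Tnfaip3 at -2.61, against Gadd45b at 4.03. Nfkbiz differed by 2.24 on its brightest probe and by -0.29 on the other. In the microbial-product response of phagocytes, 10 of 20 members were at least 2-fold lower and 3 were higher (median -1.09, percentile 0, or 2.79 with normexp background correction), with the itaconate-producing enzyme gene Acod1 at -3.34, the fungal and mycobacterial sensor gene Clec4e at -3.24, Thbs1 at -3.03 and the endotoxin co-receptor gene Cd14 at -2.15. Immediate early genes went both ways (12 of 28 higher, 7 lower; median 0.38, and -0.52 under spike-in scaling): Phlda1 was higher by 6.19, Klf4 by 6.05 and the AP-1 gene Jun by 4.22, while Fosl2 differed by -3.82.

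The glycolysis and hypoxia list was the furthest below its random lists. Of 20 members, 16 were at least 2-fold lower and 1 was higher, with a median of -1.87 (percentile 0). Beside Slc16a3 and Egln3, Hk2, the gene of a glucose-trapping hexokinase, differed by -3.85 and the mitophagy gene Bnip3 by -2.90. Cholesterol synthesis had 6 of 19 members at least 2-fold lower and 1 higher (median -0.71, percentile 0.86). Its enzyme genes Sqle and Cyp51 differed by -2.12 and -2.01, whereas Insig1, a brake on the same pathway, was higher by 3.01. The metallothionein genes Mt1 and Mt2 differed by -2.82 and -2.57. In housekeeping, the glycolytic genes Pgk1 and Gapdh differed by -2.08 and -0.89, while 12 of the 14 members stayed within 2-fold.

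Among cell type markers, those of B cells lay above their random lists with MRL/MpJ urine (median 0.85, percentile 99.73; -0.05 under spike-in scaling), although 8 of 13 stayed within 2-fold and 5 were higher, with Cr2, the complement receptor gene of mature B cells, at 2.46, Cd22 at 1.70 and Cd37 at 1.55. The spike-in shift of -0.90 takes Cd22 and Cd37 below 2-fold higher. Plasma cells had a median of 1.13 (percentile 99.49, and 0.23 under spike-in scaling), with Tnfrsf17 at 1.83, Mzb1 at 1.28 and the immunoglobulin joining chain gene Jchain at 1.22. The same shift takes Tnfrsf17, Mzb1 and Jchain below 2-fold higher. Of the 8 measured plasma cell markers, 5 were at least 2-fold higher and 1 was lower, namely Irf4, given above. Monocytes and macrophages had 0.80 (percentile 99.25; -0.10 under spike-in scaling) and neutrophils 0.73 (percentile 99.29; -0.17 under spike-in scaling), with the complement genes C1qb and C1qc at 1.29 and 1.27 and the neutrophil gene Retnlg at 1.24. Cell cycle genes had a median of 0.51 (percentile 98.42; -0.39 under spike-in scaling) with the cyclin gene Ccnb2 at 3.27, and 16 of their 22 members stayed within 2-fold. The lymphoid tissue organisation list had a median of 0.75 (percentile 98.8; -0.15 under spike-in scaling), although its brighter members were lower: the chemokine receptor genes Ccr7, Cxcr5 and Ccr6 differed by -2.29, -2.23 and -1.88, and genes above the median level alone gave -1.42. T cell markers had 0 members 2-fold apart in either direction among 14 (median 0.10; -0.80 under spike-in scaling).

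The remaining lists lay in neither tail of their random lists with MRL/MpJ urine. The median was -0.43 for inflammatory cytokines, where Il1rn, the interleukin-1 receptor antagonist gene, differed by -3.20 and Lif was higher by 1.55. Lif read 4.64 intensity units with PBS, close to the lowest signal called well above background there (4.47), so its size is uncertain. Chemokines had a median of 0.14. Of their 14 members measured on both arrays, 5 were at least 2-fold lower and 3 were higher, with Cxcl2 higher by 2.17. Medians were -0.30 for unfolded protein and amino acid stress, -0.08 for oxidative stress NRF2 targets, -0.45 for p53 targets and apoptosis, -0.11 for metal response, 0.14 for glucocorticoid targets, 0.80 for aryl hydrocarbon receptor targets and 0.26 for housekeeping. Among markers they were 0.01 for NK cells, 0.18 for dendritic cells, 0.47 for erythroid cells, 0.57 for platelets and megakaryocytes, 0.78 for stromal cells, 0.67 for endothelial cells, 0.67 for urinary tract epithelium and 0.88 for major urinary proteins and liver. Under spike-in scaling every positive median in this group was negative, as were those of NK cells, T cells, chemokines, dendritic cells, glucocorticoid targets and housekeeping when arrays were scaled by their medians. Few urine-associated markers were measured at all, namely 4 of 15 for urinary tract epithelium, 5 of 10 for major urinary proteins and liver, and 1 of 10 on the array for male accessory glands, with a difference of 0.03. That member of male accessory glands was not well above background with MRL/MpJ urine, so the size of its difference is uncertain. Mup20, a major urinary protein gene, was higher by 2.98.

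**Figure D1:**
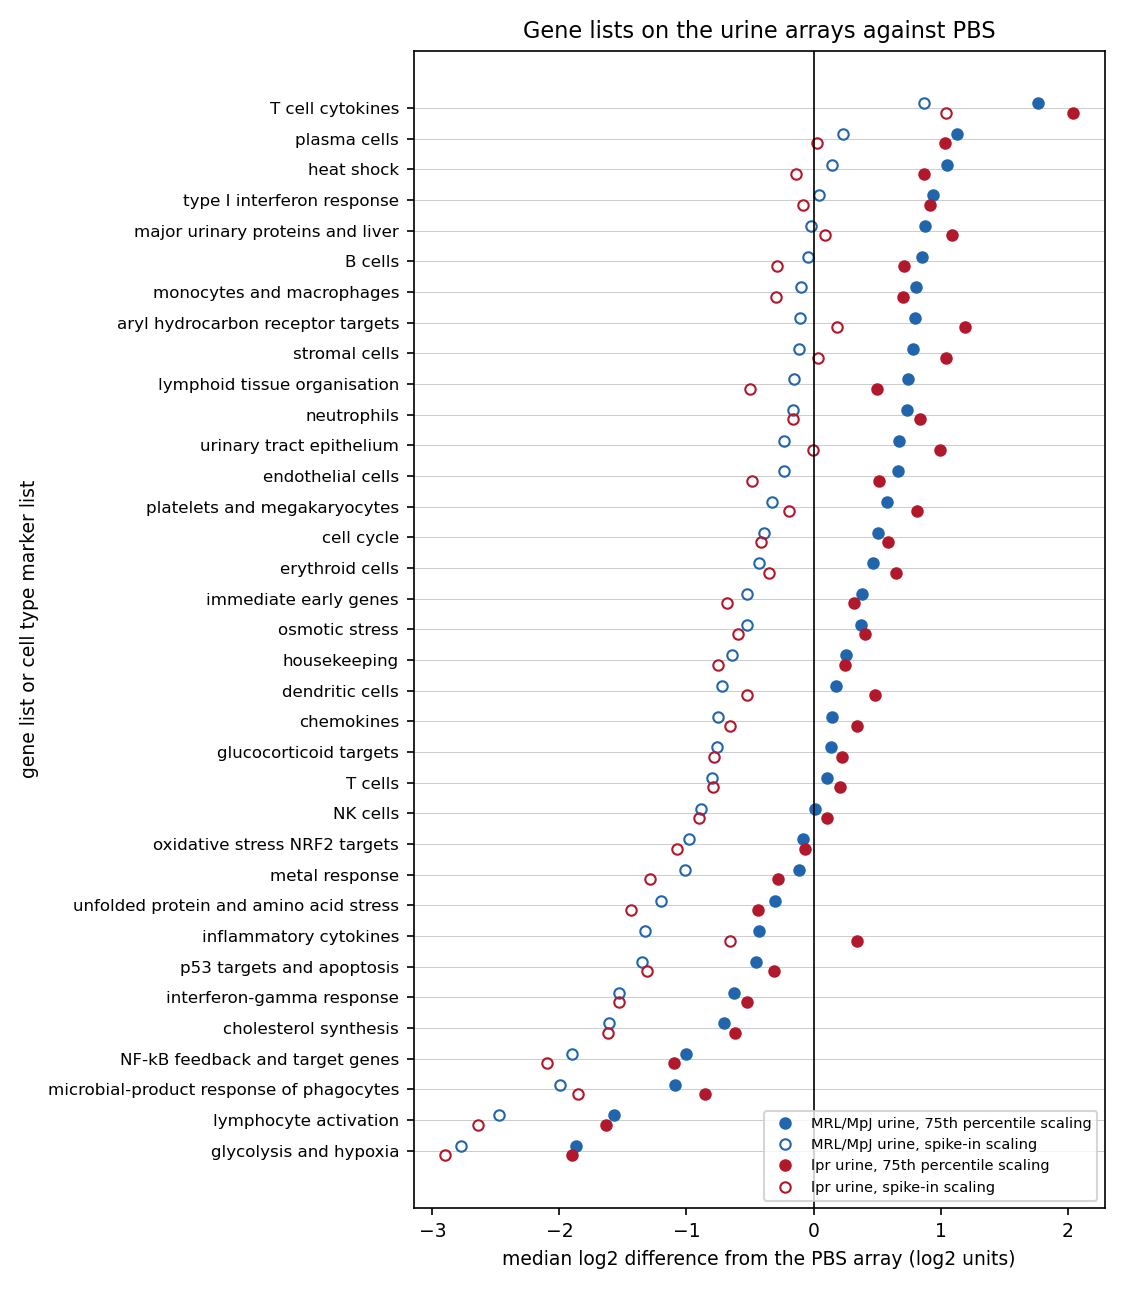
Median log2 difference from the PBS array of each list with at least 4 measured members, for MRL/MpJ urine (blue) and lpr urine (red), scaled on each array's 75th percentile (filled) or on the spike-ins (open). Glycolysis and hypoxia lay lowest under either scaling, at -1.87 and -1.90 on the 75th percentile and -2.77 and -2.90 on the spike-ins, while lists such as heat shock (1.05 and 0.87) and B cells (0.85 and 0.71) lay near or below 0 under spike-in scaling, B cells with both urines and heat shock with lpr urine.

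In all, 3318 of 19639 genes measured on both arrays were at least 2-fold higher with MRL/MpJ urine and 2181 were lower, so that 60.3% of them were higher. That share was 33.7% with arrays scaled by their medians (2090 higher, 4120 lower), 45.8% after normexp background correction (1373 higher, 1623 lower) and 12.2% under spike-in scaling (1110 higher, 7990 lower). Directions are therefore relative to the scale chosen, and genes near the middle have none. A further 1146 genes were measured on the urine array alone and 1653 on the PBS array alone. Among 1540 genes past 2-fold with several measured probes, all probes had the same direction in 78.1% and all passed 2-fold in 41.9%. Of the 15 lists in a tail of their random lists, 10 stayed there under each alternative that could move them, which scaling by the median or the spike-ins cannot, and those that did not were the microbial-product response of phagocytes, the type I interferon and interferon-gamma responses, T cell cytokines and lymphoid tissue organisation.

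The second comparison asked the same of urine from the autoimmune strain. The same genes led: Fgf18 was 829-fold higher with lpr urine than with PBS, Lsmem1 703-fold, Gadd45g 188-fold and Arc 164-fold, and Pycard was 349-fold higher on the probe described above and differed by 0.49 on the other. Oxt, the oxytocin precursor gene, was higher by 6.89 on one probe and by 2.88 on the other (chromosome 2, 130402665 to 130402724), and Gdf9, an oocyte growth factor gene, was 105-fold higher (chromosome 11, 53251307 to 53251366). Cracr2b differed by 7.08 on its highest and 0.24 on its lowest probe, Rbm44 by 6.76 and 1.16, and Orc1 by 6.57 and 4.05. The lowest was Eno2, a glycolytic enolase gene, at 44.3-fold lower (chromosome 6, 124710388 to 124710447), then Cables1 at 43.4-fold, Hilpda at 33.3-fold, Ramp3 at 29.9-fold, Ccl4 at 25.5-fold, Lrrc32 at 23.6-fold and F10 at 22.6-fold, with Dmrtb1 at -5.23 on one probe and 2.16 on the other. Trib3 and Chac1, which respond to amino acid shortage, were 21.6-fold and 21.3-fold lower. Folds of genes near background on the lpr urine array are uncertain in size. Eno2 read 7.07 intensity units there, where the lowest signal called well above background was 4.43. Of the bounds, Smim41 was at least 327-fold higher and Hcrt at least 131-fold, and Lyzl6 was at least 56.9-fold lower, Mfsd2a at least 25.4-fold and Eml1 at least 17.3-fold.

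Stress and interferon genes differed with lpr urine much as they had with MRL/MpJ urine. Heat shock had 7 of 17 members at least 2-fold higher and 0 lower (median 0.87, percentile 99.9; -0.14 under spike-in scaling), led by Hspa1b at 4.52 and Hspa1a at 3.32. Under spike-in scaling Dnaja1 (0.95) and Hspa8 (0.71) were no longer 2-fold higher, and Hspb1 was 2-fold lower (-1.12). Osmotic stress had a median of 0.41 (percentile 97.6, and -0.60 under spike-in scaling). Of its 14 members measured on both arrays, 4 were at least 2-fold higher and 1 was lower. Slc5a3 was higher by 4.45 and Sgk1 by 2.93, whereas Slc2a1 differed by -2.95. The type I interferon response had 9 of 22 members measured on both arrays at least 2-fold higher and 0 lower (median 0.92, percentile 99.96, or 95.3 among genes above the median level; -0.09 under spike-in scaling), with Isg15 at 3.78, Mx1 at 3.11 and Oas2 at 2.81. T cell cytokines had a median of 2.05 over 7 measured members (percentile 99.85), of which Il17f and Il21 were not well above background with PBS. Of the 5 measured on both arrays, 3 were at least 2-fold higher and 1 was lower. Ifng was at 4.04, Tnfsf11 at 2.04 and Il4 at 1.26, or 3.04, 1.04 and 0.26 under spike-in scaling. Gzmb was at -2.33, or -3.33 under spike-in scaling. The aryl hydrocarbon receptor targets had 1.19 over 6 measured members (percentile 98.97), with the amino acid transporter gene Slc7a5 at 3.26 and Tiparp, a feedback repressor of the receptor, at 2.02, against the receptor gene Ahr at -2.72.

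Glycolysis, lymphocyte activation, NF-kB and phagocyte response lists were again low. Glycolysis and hypoxia had 16 of 20 members at least 2-fold lower and 1 higher (median -1.90, percentile 0), with Slc16a3 at -4.31, Egln3 at -4.12 and Hk2 at -3.36, and with Tpi1 at -3.06 on its brightest probe and 1.15 on another. Lymphocyte activation had 13 of 19 members measured on both arrays lower and 2 higher (median -1.63, percentile 0), with Cd83 at -3.59, Pdcd1 at -3.27, Irf4 at -3.15 and the inhibitory receptor gene Ctla4 at -2.79. NF-kB feedback and target genes had 11 of 21 such members lower and 4 higher (median -1.10, percentile 0), with Rel at -2.59 and Tnfaip3 at -2.53 against Gadd45b at 3.97. The microbial-product response of phagocytes had 9 of 20 lower and 4 higher (median -0.86, percentile 0, or up to 10.4 under the alternatives), with Thbs1 at -3.57, Acod1 at -3.07 and Clec4e at -2.96, while Ptgs2, the inducible cyclooxygenase gene, was higher by 2.43. Among immediate early genes (13 of 28 higher, 6 lower), Phlda1 was higher by 6.08, Klf4 by 5.79, Jun by 4.14 and Fosb by 3.69. Under spike-in scaling Atf3 (-1.94), Zfp36 (-1.67) and Myc (-1.60) joined the lower members. Ier3 (0.94), Nr4a2 (0.06) and Dusp1 (0.03) were then no longer 2-fold higher. In unfolded protein and amino acid stress, the asparagine synthetase gene Asns differed by -4.14 and Ppp1r15a by 4.01.

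A group picked only after the values were seen was that of the ribosomal protein genes. With 75th percentile scaling, the 77 measured ones had a median of 0.71 with MRL/MpJ urine and 0.77 with lpr urine, and with spike-in scaling -0.19 and -0.24. Other named genes had -0.03 with each urine, or -0.93 and -1.03 under spike-in scaling. Ribosomal protein genes thus lay close together, with quartiles of 0.65 and 0.76 with MRL/MpJ urine, and above most other genes, while the direction of their own difference depended on the scaling. They are among the brightest genes, and other named genes of the same PBS signal lay near them, at 0.67 with MRL/MpJ urine and 0.73 with lpr urine under 75th percentile scaling.

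**Figure D2:**
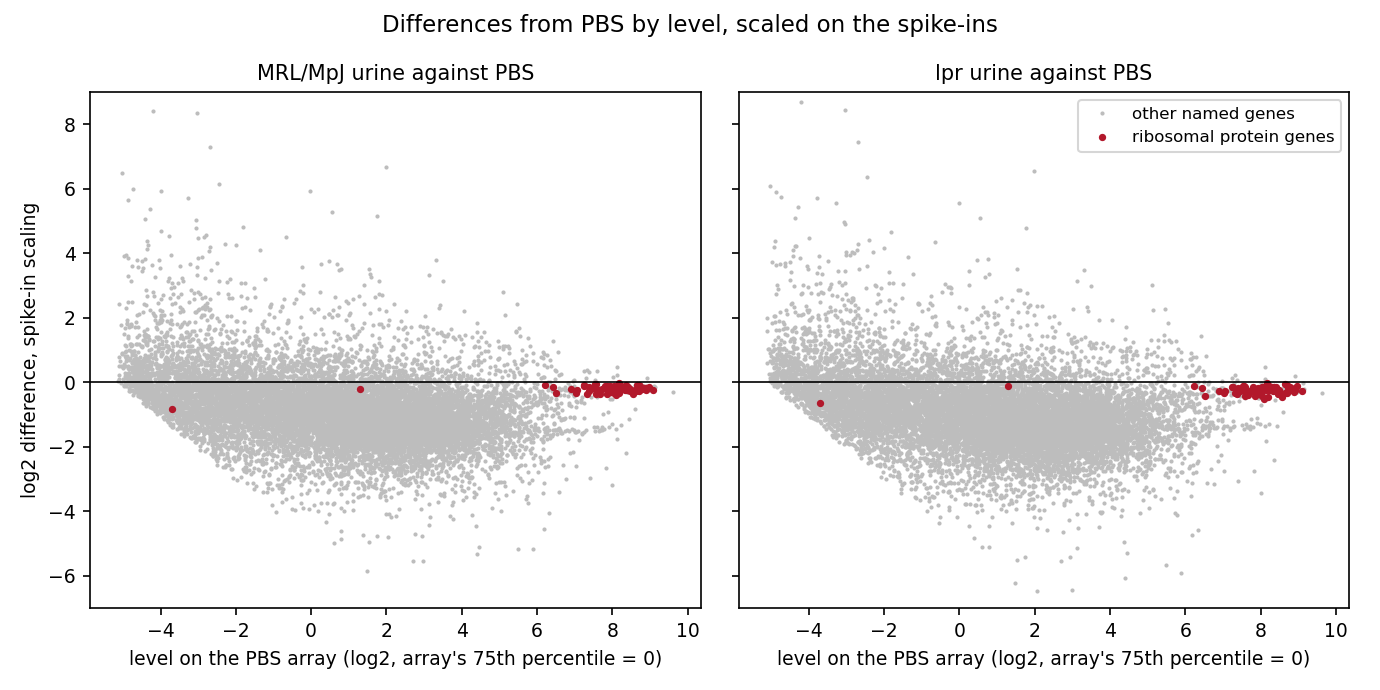
Spike-in-scaled log2 difference from PBS (vertical axes) against level on the PBS array (horizontal axes) for each named gene, MRL/MpJ urine and lpr urine in separate panels, ribosomal protein genes in red. Their medians of -0.19 and -0.24 lay above those of other named genes, -0.93 and -1.03, and under 75th percentile scaling were positive at 0.71 and 0.77.

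Cell type markers also resembled the first comparison. B cells had a median of 0.71 (percentile 97.7; -0.29 under spike-in scaling), plasma cells 1.03 (percentile 99.25; 0.03 under spike-in scaling), neutrophils 0.84 (percentile 99.7; -0.17 under spike-in scaling) and cell cycle genes 0.59 (percentile 99.24; -0.41 under spike-in scaling). Cr2 was higher by 2.33, Tnfrsf17 by 1.54, Retnlg by 1.30 and Ccnb2 by 3.46, while Mpo, a granule enzyme gene of early neutrophils, differed by -1.19. Of the 8 measured plasma cell markers, 5 were at least 2-fold higher and 2 were lower, including Irf4 at -3.15.

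With lpr urine the remaining lists lay in neither tail of their random lists. Inflammatory cytokines had a median of 0.34, with Il1rn at -3.19 and Lif, which was near background on the PBS array, at 2.03 (1.03 under spike-in scaling). Chemokines had a median of 0.34, with Cxcl2 at 3.02. Of their 14 members measured on both arrays, 6 were at least 2-fold lower, with Ccl4 the lowest, and 3 were higher. Medians were -0.53 for interferon-gamma response, 0.32 for immediate early genes, 0.50 for lymphoid tissue organisation, -0.44 for unfolded protein and amino acid stress, -0.07 for oxidative stress NRF2 targets, -0.31 for p53 targets and apoptosis, -0.28 for metal response, 0.22 for glucocorticoid targets, -0.62 for cholesterol synthesis and 0.25 for housekeeping. Among markers they were 0.21 for T cells, 0.10 for NK cells, 0.71 for monocytes and macrophages, 0.48 for dendritic cells, 0.65 for erythroid cells, 0.81 for platelets and megakaryocytes, 1.04 for stromal cells, 0.52 for endothelial cells, 1.00 for urinary tract epithelium and 1.09 for major urinary proteins and liver. Under spike-in scaling every positive median in this group was negative other than those of stromal cells (0.04) and of major urinary proteins and liver (0.09), and median scaling turned those of inflammatory cytokines, chemokines, immediate early genes, glucocorticoid targets, housekeeping, T cells and NK cells. The 1 measured member of male accessory glands, Spink1, was higher by 1.00 and differed by -0.0046 under spike-in scaling.

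In all, 3578 of 19368 genes were at least 2-fold higher with lpr urine than with PBS and 2319 were lower, a higher share of 60.7%. The share was 33.5% with median scaling (2156 higher, 4276 lower), 43.1% after normexp background correction (1423 higher, 1876 lower) and 11.01% under spike-in scaling (1065 higher, 8612 lower). On the lpr urine array alone, 1083 genes were measured, and on the PBS array alone 1925. All probes had the same direction in 77.2% of 1634 genes past 2-fold with several measured probes. Of the 13 lists in a tail, 7 stayed there under each alternative that could move them, and those that did not were the microbial-product response of phagocytes, the type I interferon response, T cell cytokines, osmotic stress, aryl hydrocarbon receptor targets (percentile 80.3 at the lowest) and B cells.

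Across the 19128 genes measured on all 3 arrays, the differences of both urine arrays from the PBS array were nearly the same. From Fgf18 and Gadd45g at the top to Ccl4 and Slc16a3 at the bottom, genes lay close to the line of equal difference, with a Pearson correlation of 0.979 and a Spearman correlation of 0.975 across genes, which are not independent replicates. Because both responses share the PBS array, arrays without any change would still give a correlation of 0.5003 from spot noise, as 100 simulations showed. The covariance was 1.30 against 0.015 in those simulations, a difference of 1.28. Of genes at least 2-fold higher, 3276 with MRL/MpJ urine and 3526 with lpr urine, 3007 were shared where independent sets would share 604. Of those lower, 2102 and 2297, the shared number was 1938 against 252. No gene was 2-fold higher with one urine and 2-fold lower with the other. With 1 PBS array, controls could not be split between the comparisons. Anything that set this array apart enters both differences, and the simulations held spot noise only. Part or all of the excess in correlation and overlap may therefore come from that shared control.

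**Figure D3:**
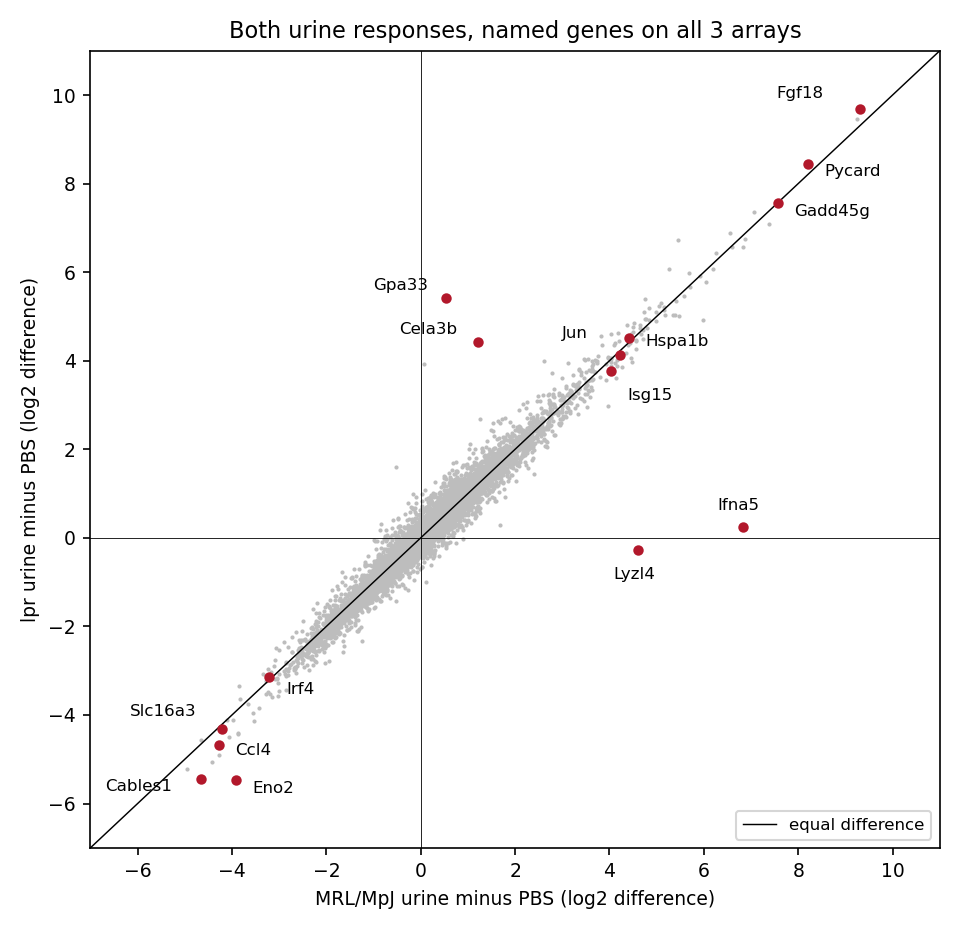
Log2 difference from PBS with lpr urine (vertical axis) against that with MRL/MpJ urine (horizontal axis) for each named gene measured on all 3 arrays (grey), with the line of equal difference and labelled genes in red. Most genes follow the line (Pearson correlation 0.979 over 19128 named and unnamed genes), while Ifna5 and Lyzl4 were high with MRL/MpJ urine alone and Gpa33 and Cela3b with lpr urine alone. Pycard is drawn from its brightest probe, which lies on the strand opposite to its other probe.

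The third comparison asked which genes tell lpr urine from MRL/MpJ urine. The clearest group was the microbial-product response of phagocytes, whose median of 0.19 (0.087 under spike-in scaling) lay above all 10000 random lists although 0 of its 20 measured members reached 2-fold. Ptgs2 was 1.92-fold higher with lpr urine, Arg2, the gene of the inducible arginase of mitochondria, differed by 0.72 and Cd14 by 0.45, against Thbs1 at -0.54. Arg2 and Cd14 were lower than with PBS on both urine arrays, at -0.89 and -1.70 with lpr urine. Il1b, which encodes interleukin-1 beta, was 1.91-fold higher, with its 3 probes between 0.21 and 1.02. The inflammatory cytokines had a median of 0.13 (percentile 99.1, but 78.8 at the lowest under the alternatives, and 0.025 under spike-in scaling), with Lif at 0.48. Lif read only 7.48 and 9.12 intensity units with MRL/MpJ and lpr urine, so the size of its difference is uncertain. The neutrophil chemokine genes Cxcl1 and Cxcl2 differed by 0.90 and 0.85, whereas the chemokine list as a whole had a median of 0.01. Immediate early genes had a median of 0.09 (percentile 99.99; -0.0086 under spike-in scaling), with Fos at 0.82, the orphan receptor gene Nr4a1 at 0.68, Ier3 at 0.65 and Maff at 0.58.

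Other lists in a tail left it under at least 1 alternative. T cells had a median of 0.09 (percentile 99.7; -0.015 under spike-in scaling), with the CD8 genes Cd8b1 and Cd8a at 0.18 and 0.17. B cells had -0.08 (percentile 1.56), with Blk at -0.22, and monocytes and macrophages -0.15 (percentile 0.30), with the monocyte chemokine receptor gene Ccr2 at -0.45 and Mrc1 at -0.30 but Cd68 at 0.50. Glycolysis and hypoxia had -0.08 (percentile 1.69), with Hk2 at 0.49 and Adm at -0.41. Aryl hydrocarbon receptor targets had 0.16 over 6 measured members (percentile 97.9), with Tiparp at 0.45. Major urinary proteins and liver had 0.52 over 5 measured members (percentile 99.2), with the liver genes Serpina1a and Apoa1 at 0.53 and 0.52 but Mup20 and Mup3 at -0.30 and -0.19, and members above the median level gave -0.19. The percentiles of the phagocyte and immediate early lists stayed in the upper tail under each alternative that could move them.

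**Figure D4:**
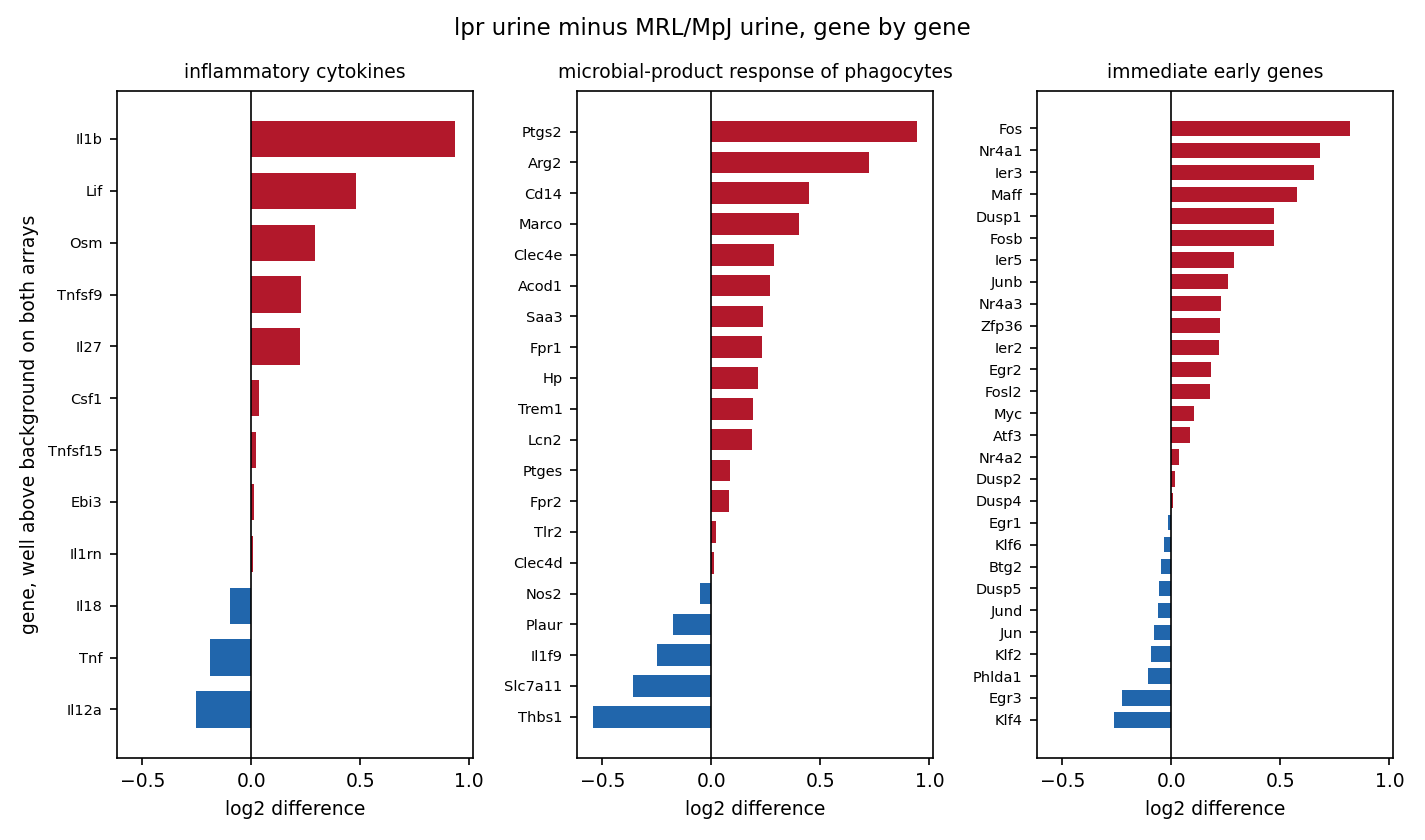
Log2 difference of lpr urine minus MRL/MpJ urine (horizontal axes) for each member of 3 lists that was well above background on both arrays, red where higher and blue where lower with lpr urine under 75th percentile scaling. Ptgs2 (0.94), Il1b (0.93) and Fos (0.82) had the largest differences and Thbs1 (-0.54) the lowest, and spike-in scaling would move each bar left by 0.10, which turns the shortest red bars and the median of the immediate early list.

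Among the largest single differences between the urines, those of Ifna5, Lyzl4, Gpa33 and Cela3b rested on 1 measured probe each and on a signal far higher on 1 array than on the others. Ifna5 read 9.95, 620.1 and 5.67 intensity units with PBS, MRL/MpJ urine and lpr urine, and was 95.5-fold lower with lpr urine than with MRL/MpJ urine. Lyzl4, a lysozyme-like gene, read 27.9, 374 and 11.05 (29.6-fold lower; chromosome 9, 121487028 to 121487087). Gpa33, the gene of an intestinal surface antigen, was 29.5-fold higher with lpr urine (29.8, 23.8 and 613; chromosome 1, 168096513 to 168096572) and Cela3b, a pancreatic elastase gene, 9.23-fold higher (chromosome 4, 136977835 to 136977894). Actr3b was higher by 3.85 on one probe and differed by -0.35 on the other, and Hivep1 was 4.35-fold higher. Smaller differences were those of Gdf9 (1.27), Tac2 (1.01), Trim69 (0.97), Fam83d (0.94), H2ac6 (-1.05), Hoxaas2 (-0.996) and Fn1, the fibronectin gene (-0.75), along with Ramp3 (-0.63), Rasd1 (-0.58) and Mpo (-0.58). Topbp1 ranged from -0.93 to -0.04 over 4 probes and Usp3 from -0.69 to 0.06. Of the bounds, Krt14 was at least 53.2-fold higher with lpr urine, Lmod2 at least 12.4-fold and Peg10 at least 5.15-fold, and Slc22a26 was at least 44.4-fold lower, Csn1s2a at least 27.6-fold and Adam3 at least 11.01-fold.

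In the remaining lists the 2 urines lay close together. Their medians were 0.0085 for NF-kB feedback and target genes, 0.01 for type I interferon response, -0.03 for interferon-gamma response, -0.07 for lymphocyte activation, 0.21 for T cell cytokines, -0.04 for lymphoid tissue organisation, -0.01 for osmotic stress, 0.03 for heat shock, -0.06 for unfolded protein and amino acid stress, -0.02 for oxidative stress NRF2 targets, 0.04 for p53 targets and apoptosis, -0.09 for metal response, 0.02 for glucocorticoid targets, -0.01 for cholesterol synthesis, 0.04 for cell cycle and -0.00031 for housekeeping. Among markers they were -0.10 for plasma cells, 0.00058 for NK cells, 0.08 for neutrophils, -0.10 for dendritic cells, 0.06 for erythroid cells, 0.14 for platelets and megakaryocytes, 0.14 for stromal cells, 0.0028 for endothelial cells and 0.30 for urinary tract epithelium. With spike-in scaling, positive medians under 0.10 in this group were negative. The 1 measured member of male accessory glands was higher by 0.97, but it was not well above background on the MRL/MpJ urine array, so the size is uncertain.

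Of 20012 genes measured on both urine arrays, 68 were at least 2-fold higher with lpr urine and 12 were lower. In the simulated arrays of this comparison, spot noise alone put 7 unchanged genes past 2-fold. Of the measured genes past 2-fold, 85.0% were thus higher, and under spike-in scaling the share was 55.1% (38 higher, 31 lower). After normexp background correction the numbers were 6 and 3. A further 449 genes were measured with lpr urine alone, 49 of them with a bound of at least 2-fold, and 786 with MRL/MpJ urine alone, 31 with such a bound. The 7 genes past 2-fold with several measured probes had all probes in 1 direction in 4 cases.

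Fas, which encodes the death receptor that the lpr donors lack, was 2.16-fold lower in the spleen cells with MRL/MpJ urine and 2.03-fold lower with lpr urine than with PBS (probe on chromosome 19, 34402164 to 34402223), on the 1 of its 2 probes that was measured, while the mean of both probes gave -0.12 and 0.016. Fasl, the gene of its ligand, differed by -0.42 and -0.21 (chromosome 1, 163711056 to 163711115). Between the urines, Fas differed by 0.09, or -0.02 under spike-in scaling, and Fasl by 0.21.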

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

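The results that moved or turned are grouped by setting, higher before lower, for MRL/MpJ urine against PBS, lpr urine against PBS, and lpr urine against MRL/MpJ urine. With normexp background correction 1373 and 1423 genes were at least 2-fold higher with the urines, and 6 and 3 were higher and lower between them. Scaling by the median gave 2090 and 4120 genes, then 2156 and 4276, which its constant shift of every difference explains by construction. Quantile normalisation gave 21 genes lower between the urines. Genes measured on at least 1 array gave 238 and 195 between the urines. Without a filter on dim genes there were 6817 and 15040 genes higher against PBS, and 1100 and 741 between the urines. The 75th percentiles were 157.5 intensity units with PBS, 86.6 with MRL/MpJ urine and 75.7 with lpr urine. A gene of equal signal on the PBS and lpr urine arrays therefore counted as 2-fold higher by construction, but not with MRL/MpJ urine. Genes above the median level gave 1093 and 1213, 1138 and 1295, and 8 and 2, and turned lymphoid tissue organisation with MRL/MpJ urine to -1.42 and major urinary proteins and liver between the urines to -0.19. Their correlation was 0.991, and that after normexp was 0.988. The mean of a gene's probes gave 25 genes lower between the urines and, with lpr urine against PBS, turned Aen to -0.74 and Fas to 0.016. The 1.5-fold rule gave 6126 and 4428, 6461 and 4427, and 464 and 206. Named genes without ribosomal protein genes were 1823 and 1940 higher against PBS, and 25 and 7 between the urines. Spike-in scaling gave 1110 and 7990, 1065 and 8612, and 38 and 31. Among lists in a tail, its constant shift turned, with MRL/MpJ urine, lymphoid tissue organisation (-0.15), cell cycle (-0.39), B cells (-0.045), monocytes and macrophages (-0.10) and neutrophils (-0.17). Lists outside the tails also changed sign, as given in the Results, and are not repeated here. Of the lists in a tail with lpr urine, spike-in scaling turned type I interferon response (-0.086), osmotic stress (-0.60), heat shock (-0.14), cell cycle (-0.41), B cells (-0.29) and neutrophils (-0.17), and between the urines immediate early genes (-0.0086) and T cells (-0.015). For the settings other than constant shifts, the cause was not tested beyond that effect of scaling on genes of equal signal. A list median counted as moved where it shifted by more than 1 SD of its random lists' medians and was not among those given above as turned. Those turned are counted apart: 13 under spike-in scaling and 2 among genes above the median level. Of 105, 31 moved under normexp, 53 under median scaling, 7 under quantile normalisation, 11 without a filter on dim genes, 14 with the mean of probes, 8 with both arrays required and 86 under spike-in scaling, while 0 moved without ribosomal protein genes or with dim levels raised to the lowest measured level. Among genes above the median level 26 of 99 moved, beside the 2 that turned. Of 468 values of named genes, 436 moved under normexp, 311 under median scaling, 217 under quantile normalisation, 170 with the mean of probes, where a further 2 turned, and all 468 under spike-in scaling, a named gene counting as moved beyond the median SD of repeated spots. For a gene dim on an array, signal over background gives a bound and no size.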

Other observations

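The patterns below were noticed in the results first, and the tests of hybridisation, labelling, bright signals, distant neighbours, dose and spot noise were chosen only after the result was seen, whereas those of degradation, dim probes and near neighbours were written down before they were run. Intervals are 95% bootstrap intervals (2000 draws) over genes or probes of these single arrays. They leave out differences between wells and arrays.

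Among genes not yet described, the antioxidant genes Srxn1 and Slc7a11, both NRF2 targets, differed by -2.85 and -1.28 with MRL/MpJ urine and by -3.45 and -1.64 with lpr urine, whereas the glutathione transferase gene Gsta3 was higher by 1.14 and 1.18. The p53-linked kinase gene Plk2 was higher by 3.92 and 3.56, and Bbc3, which encodes the cell death protein PUMA, differed by -1.86 and -1.75. Per1, a clock gene that glucocorticoids induce, differed by -2.37 and -2.36. The cytotoxic granule gene Nkg7 was higher by 2.68 and 2.82, and the actin-binding smooth muscle gene Tagln by 3.18 and 3.32. The dendritic cell transcription factor gene Zbtb46 differed by -2.23 and -2.45, while the dendritic cell receptor gene Clec9a was higher by 1.85 and 1.49. In the platelet list, the integrin gene Itgb3 differed by -2.49 and -2.75.

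Ribosomal protein genes kept their signal against the spike-ins on both urine arrays (-0.19 and -0.24) while other named genes lay lower (-0.93 and -1.03). Other genes of the same PBS signal lay only -0.041 (95% interval -0.094 to -0.012) and -0.074 (-0.10 to -0.03) from them, so compression of bright signals could give the pattern, although 339 other bright genes, less bright as a group, lay -0.46 (-0.65 to -0.33) and -0.51 (-0.68 to -0.38) from them. Weaker hybridisation or scanning was argued against, as the spike-ins differed by 0.046 and -0.060, but weaker labelling of the sample RNA cannot be told apart by these values because the labels do not say whether the spike-ins went in before labelling. Degradation read from the 3' end was argued against, since 5' probes stood above 3' probes by 0.090 and 0.13. Whether abundant messages of many kinds were kept in the cells themselves stays open.

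Probes for long intergenic RNAs exceeded gene probes of the same PBS level by 0.29 and 0.37 with the urines, which argues against weaker differences of dim probes as the cause. Within 20 kb downstream of active genes, those on the gene's strand had medians of 1.03 and 1.02 and those on the opposite strand 0.34 and 0.43, an excess of 0.70 (0.41 to 0.99) and 0.59 (0.33 to 0.84) that transcripts running past 3' ends would give and that strandless genomic DNA would not. With the active gene 20 to 100 kb away, the excess was 0.22 (0.07 to 0.42) and 0.33 (0.14 to 0.51), which fits such transcripts, while a part from genomic DNA cannot be told apart there because the lower limits are close to 0. These 2 groups on the gene's strand held 382 and 313 of 2533 probes with MRL/MpJ urine, while the 1221 and 1220 probes with no active gene within 100 kb had medians of 0.35 and 0.44 under 75th percentile scaling, near those of the opposite strand. For that larger group neither explanation was tested, so the source of its differences stays open, and how the excess divides between the groups was not measured.

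Inflammatory and phagocyte response genes were mostly higher with lpr urine than with MRL/MpJ urine, namely 24 of 32 members (median 0.14), with Ptgs2 at 0.94 and Il1b at 0.93, but under spike-in scaling only 16 of 32 were (median 0.03). Under 75th percentile scaling, 14 of the 32 were higher with lpr urine than with MRL/MpJ urine and lower with MRL/MpJ urine than with PBS. A stronger dose of the response to MRL/MpJ urine cannot be told apart, since the 50% of members with the sign of that response come from lists picked for the pattern and from differences that share an array. Spot noise cannot be told apart either, as their median absolute difference was 0.23 beside a spot noise of 0.13 at their levels, and noise between arrays was not measured. A difference in urine content between the strains, such as endotoxin, cytokines or immunoglobulin, may likewise account for it and remains open as untested, as does a difference between wells.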
